A study of Gallus gallus and Melopsittacus undulatus with 6 samples.

How the data were processed

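Nuclei were isolated from frozen retina of 6 species, and droplet-based 3' RNA libraries were made from them, with 1 library per species. The species were chicken, budgerigar and duck, which are birds, Oreochromis and snakehead, which are fish, and cat. The protocol in the labels describes freezing and lysis to nuclei, whereas the series' design text calls the samples fresh, so the droplets are called nuclei here. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger and filtered to called barcodes, with no further normalization. The files' headers give Cell Ranger 7.1.0, whereas the submitters' processing notes give version 3.0.2 and name the chicken build GRCg7b for all 6 samples, so the builds behind the other species' counts are not known.

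Gene symbols decided what could be named. The deposited feature tables gave symbols for 13909 of 29558 features in the chicken, 18158 of 29099 in the cat and 10219 of 42646 in Oreochromis. Symbols were given for 223 of 16569 features in the budgerigar, 259 of 17971 in the duck and 0 of 22593 in the snakehead. The reference table of symbols held no identifier of those 3 libraries, so their clusters kept numbers. Of 149 fixed marker genes, 124 carried a symbol in the chicken, 131 in the cat and 80 in Oreochromis. Symbols were matched in capitals. In Oreochromis, a final a or b of a duplicated fish gene was removed and the copies were summed.

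Nuclei with at least 500 UMIs and 200 genes were kept, and in the chicken and the cat, where mitochondrial genes carried names, those with at most 10% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5. Its own threshold marked 647 chicken and 1145 budgerigar nuclei, but 1 in Oreochromis and 0 in the other 3 libraries. The 6% of nuclei with the highest scores were therefore removed from every library, a rule chosen after seeing the data. Each library was clustered on its own: counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes outside the comparison lists were reduced to 30 principal components, and Leiden clustering (igraph 0.11.9) ran at resolution 1 on 15 nearest neighbours with seed 1.

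Clusters were named from 16 marker lists, and a class name below stands for nuclei that are like that class in these markers only. Only markers with at least 20 UMIs in a library were scored. A marker counted as raised at 1 log2 unit above the 25th percentile of the library's clusters, with 20 CPM added, and with a UMI in at least 10% of the cluster's nuclei. A name needed 3 raised markers, the highest mean score of all classes, a lead of 0.3 over the next class and 50% of that class's best score in the library. A cluster led by more markers of another class than of its own stayed unnamed. These scoring thresholds were chosen after seeing the data. The weak-score thresholds kept 3.88% of chicken nuclei out of the amacrine class and 1.35% of cat nuclei out of the horizontal class. In Oreochromis they kept 3.28% of nuclei out of the bipolar class and 7.73% out of the oligodendrocyte class. A further 0.870% of cat nuclei scored highest for rod markers and stayed unnamed because genes of another class led. Names rebuilt in this way need not match those the study gave.

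Shares carry exact 95% binomial (Clopper-Pearson) intervals, and levels in CPM, the UMIs of a gene per 1e6 UMIs of its class, carry exact Poisson intervals. Both cover counting error only, since there is 1 library per species, and no test was made between species. A count of 0 was given a floor of 3 counts. A cone nucleus was assigned to the cone opsin with most UMIs, at least 1 and more than any other, and the share of nuclei outside the photoreceptor classes with a UMI of that opsin was taken as background.

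For comparisons of classes, UMIs were summed per library and class, and the sums of libraries with at least 30 nuclei of each class and with symbols were tested. Only the chicken and the cat met this. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with species as a block, TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. With 4 sums it has 1 residual degree of freedom, and sums of nuclei of 1 library are not replicates of a species. A gene with 0 UMIs in both classes of 1 library is compared within the other library alone. The alternatives were DESeq2 1.42.0 with its Wald test, RLE size factors, no expression filter, at least 1000 UMIs per nucleus, doublets kept, exact symbols, resolutions 0.5 and 2, assignment of single nuclei by marker UMIs, stricter opsin calls and nuclei thinned to 1000 UMIs. Further alternatives, namely clusters made from genes other than the one tested and bipolar with amacrine nuclei as the neurons, were chosen after seeing the data. Data were simulated with 1 mean level per gene for all 4 sums and the common spread of each fit. Spreads of single genes and the real differences between libraries were left out, so recovery in the real data may differ. In all, 200 genes were changed among 8600 or 10340. Of 50 changed 16-fold, the test recovered 13 for cones against rods and 22 for Müller glia against neurons. At 4-fold it recovered 0 of 50 in both.

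Tests, markers, 13 comparison lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the largest change in each direction among those that passed over all genes and kept their sign in every library, and up to 4 measured members of each list with the smallest p. Since no gene passed over all genes, the named genes come from the lists. Other list members are named where they passed, which was a choice made after their values were seen. Some genes that the rule names are not reported here. The planned tests of birds against fish could not be made, because the chicken was the only bird with named classes and no rods, cones or Müller glia could be named in either fish.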

Results

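Single-nucleus RNA profiles of the retina were collected from 6 species, with 1 library each: 3 birds (chicken, budgerigar, duck), 2 fish (Oreochromis, snakehead) and 1 mammal (cat). The series concerns how retinal cell types differ between animals that see colour differently. The libraries held 38080574 UMIs in the chicken, 12142090 in the budgerigar, 10126598 in Oreochromis, 6709732 in the snakehead, 36497170 in the duck and 23401192 in the cat. After filtering, 13774 chicken, 9385 budgerigar, 5785 Oreochromis, 5495 snakehead, 17510 duck and 10112 cat nuclei remained. The snakehead kept 59.4% of its barcodes, and its median nucleus held 704 UMIs, against 1932 in the chicken and 1279 in the cat. There are no replicates of any species, so every interval below covers counting error in 1 retina library.

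The chicken library was rich in amacrine cells, and the cat library was mostly rods. Amacrine cells, the inhibitory interneurons of the inner retina, made up 32.6% of chicken nuclei (95% binomial interval 31.8 to 33.4). They made up 5.10% of cat nuclei (4.68 to 5.55). Bipolar cells, which carry photoreceptor signals inward, were 15.4% (14.8 to 16.0) in the chicken and 7.29% (6.79 to 7.81) in the cat. Müller glia, the radial glia of the retina, were 13.7% (13.2 to 14.3) and 6.27% (5.80 to 6.76). Retinal ganglion cells, the output neurons, were 8.42% (7.96 to 8.90) in the chicken and 0.396% (0.283 to 0.538) in the cat. Horizontal cells were 2.99% (2.71 to 3.29) and 1.52% (1.29 to 1.78). Among nuclei with at least 1000 UMIs the bipolar order turned, with 9.05% (8.51 to 9.60) in the chicken and 10.5% (9.83 to 11.3) in the cat. There horizontal cells were 2.17% (1.90 to 2.46) and 2.23% (1.90 to 2.61), and at resolution 0.5 they were 1.36% (1.17 to 1.57) and 1.52%, so their order is not settled. Microglia and other immune nuclei were 2.96% (2.69 to 3.26) and 0.208% (0.129 to 0.317), and 2.47% and 0.394% with at least 1000 UMIs. Oligodendrocytes, the myelinating glia, formed 2.95% (2.68 to 3.25) of chicken nuclei, and no cat cluster was named so. Unnamed clusters held 5.53% of chicken and 4.00% of cat nuclei. At resolution 2 they held 15.5% and 4.33%, and among nuclei with at least 1000 UMIs 11.1% and 5.54%. The leading genes of 1 cat rod cluster, with 1701 nuclei, were mitochondrial.

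**Figure D1:**
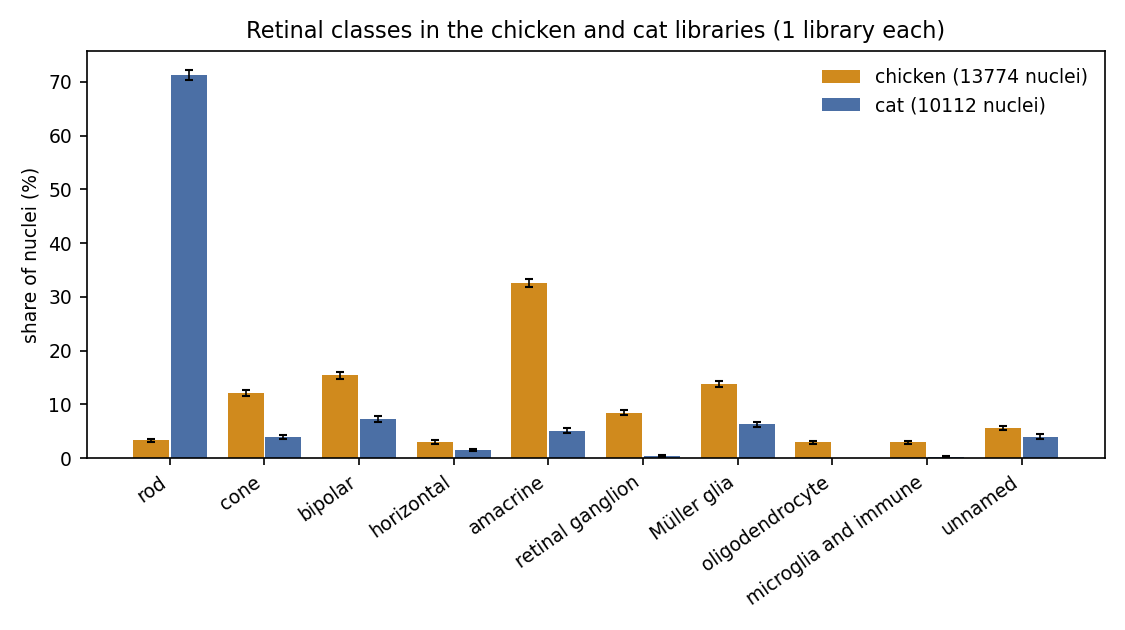
Share of nuclei (%) in each retinal class of the chicken (13774 nuclei) and cat (10112 nuclei) libraries; bars are shares, and error bars are exact 95% binomial intervals for counting error only. Rods were 71.3% of cat nuclei and 3.31% of chicken nuclei.

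In Oreochromis, 69.2% of nuclei (68.0 to 70.4) stayed unnamed. Named clusters were like oligodendrocytes (16.8%, 15.9 to 17.8), amacrine cells (13.3%, 12.5 to 14.2) and retinal ganglion cells (0.657%, 0.465 to 0.901). These shares changed with the processing: the amacrine share was 0.796% with doublets kept and 1.35% at resolution 2, and the ganglion cell class was empty under 3 of the alternatives. CNGA1, a subunit of the rod cyclic nucleotide-gated channel, had UMIs in all 31 clusters, and stood at 669 CPM in amacrine nuclei and 803 CPM in oligodendrocyte nuclei. It was highest, at 1686 CPM (1544 to 1837), in an unnamed cluster of 391 nuclei whose best score was that of rods, against a median of 778 CPM over clusters. CNGA1 is itself among the rod markers, so that score follows in part from its level. No cluster met the rules for the names rod or cone. The name cone could not be reached, since only 1 cone marker was scored and a name needed 3. For rods 3 markers were scored, so all 3 had to be raised. The lack of these names therefore does not show that the cells were absent.

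Rods, the photoreceptors of dim light, and cones, those of colour, were in opposite balance in the 2 libraries in which both were named. In the chicken, 456 rods and 1673 cones gave a rod share of photoreceptors of 21.4% (95% binomial interval 19.7 to 23.2). In the cat, 7210 rods and 396 cones gave 94.8% (94.3 to 95.3). Cone arrestin (ARR3) stood at 108 CPM (98.5 to 117) in chicken cones and 8.75 (3.52 to 18.0) in chicken rods, and at 8613 CPM (8444 to 8785) in cat cones and 19.2 (16.4 to 22.3) in cat rods. ARR3 was among the markers that named these classes. The UMI minimum can set such shares, since the median cat rod held 1040.5 UMIs and the median cat cone 2687.5. Rods made up 79.6% of all named neurons in the cat and 4.43% in the chicken.

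Cone types are told apart by the opsin that they express. In the cat, 85.9% of 396 cones (82.0 to 89.1) were assigned to OPN1LW, the long-wavelength cone opsin. A further 7.07% (4.75 to 10.1) were assigned to OPN1SW, the short-wavelength cone opsin. Among cat nuclei outside the photoreceptor classes, 6.42% held an OPN1LW UMI and 0.618% an OPN1SW UMI, at a median of 3596 UMIs against 2687.5 in cones. In the chicken, 15.5% of 1673 cones (13.8 to 17.3) were assigned to OPN1MSW, the green-sensitive opsin. Its background was 1.37%, at a median of 1927 UMIs against 2311 in cones. The other cone opsins of the chicken carried no symbol in the tables used here. The chicken share is therefore that of cones with at least 1 OPN1MSW UMI, with no other opsin to compete as in the cat, and the remaining chicken cones could not be typed. With every nucleus thinned to 1000 UMIs, the shares were 10.3% for chicken OPN1MSW (background 0.622%), 71.4% for cat OPN1LW (2.01%) and 5.82% for cat OPN1SW (0.191%). Thinning left out 92 chicken cones and 1 cat cone as too shallow.

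Which genes set cones apart from rods across species was asked of the chicken and the cat together. No gene passed over all 8575 genes tested, so the calls that follow are those of lists fixed beforehand, adjusted over the list alone. Each list was adjusted separately and nothing was adjusted across lists, so whether a gene passed depends in part on its list. Among photoreceptor transcription factors, RXRG, a retinoid receptor of developing cones, was higher in cones by 6.77 log2 units (SE 1.56). The homeobox gene RAX was higher by 5.37 (SE 0.71), and the repressor PRDM1 by 4.94 (SE 0.69). Rods were higher in ESRRB, an orphan nuclear receptor needed for rod survival (cones against rods −5.51, SE 0.83), and in RORB, a nuclear receptor upstream of rod fate (−3.64, SE 0.73).

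Of 26 measured photoreceptor transcription factors, 7 were higher and 4 lower in cones, adjusted over the list alone. The other higher ones were LHX4 (5.77), SALL1 (5.80), SALL3 (4.49) and TBX2 (3.26), and the other lower ones SAMD11 (−4.40) and MAFA (−6.76). SALL1, SALL3 and TBX2 no longer passed with doublets kept, nor SALL1 and SALL3 with RLE size factors, nor MAFA with DESeq2. The thyroid hormone receptor THRB, a regulator of cone types, did not pass (1.94, SE 0.83, list-adjusted p 0.121). In cat rods SALL1 and SALL3 had 0 UMIs, so their cat ratios are lower bounds. TBX2 rested on 4 and 3 UMIs in cat cones and rods. MAFA had 0 UMIs in both cat classes, so its call rests on the chicken, with 546 CPM in rods and 4.26 in cones. Of 16 phototransduction genes beyond the markers, 4 were higher and 2 lower. GNB3 (4.84, SE 1.10), the cone transducin beta subunit, was higher in cones, and GNB1 (−4.60, SE 0.69), that of rods, was lower. CNGA3, the cone channel subunit, was higher by 5.31 (SE 1.30), and the calcium sensor GUCA1C by 6.01 (SE 1.62). The sodium-calcium exchangers parted likewise, with SLC24A2 higher by 5.84 (SE 1.61) and SLC24A1 lower (−5.15, SE 1.16). None of these 6 passed with doublets kept, and with RLE size factors GNB1 alone did. Per library, the GNB1 ratio of cones to rods was −4.82 (−5.09 to −4.55) in the cat and −4.84 (−5.07 to −4.61) in the chicken. The others of these 6 kept their sign but differed more between the libraries. With a small constant added to each level, SLC24A2 stood at 7.77 in the cat and 3.34 in the chicken. GUCA1C stood at 7.19 and 3.61, CNGA3 at 6.42 and 3.08, GNB3 at 5.69 and 2.92, and SLC24A1 at −3.63 and −6.85.

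Among other lists, 1 of 11 visual cycle genes was higher in cones (RBP4, a retinol carrier, 2.52, SE 0.48), which did not pass with RLE size factors. So was 1 of 13 outer segment genes (C1QTNF5, 3.47, SE 0.65), which rests on the cat, since the chicken had 1 UMI in cones and 0 in rods. C1QTNF5 did not pass with doublets kept or with DESeq2. Of 12 homeostasis genes of Müller glia, SLC6A13 was higher (4.45, SE 0.71), again on the cat alone with 0 chicken UMIs in both classes. In that list VEGFA (−2.70, SE 0.59) and KCNJ2 (−2.80, SE 0.67) were lower, on 1 and 30 cat UMIs for VEGFA and 0 and 3 for KCNJ2 in cones and rods. None of these 3 passed with DESeq2. No member passed in 7 lists, whose members with the smallest p are given here with fitted log2 values. For 18 ribbon synapse genes these were PPEF2 (−2.32), CACNA2D1 (4.43), ELFN1 (−1.47) and ELFN2 (1.03). For 7 carotenoid and oil droplet genes they were FABP7 (−2.78), STBD1 (1.65), DGAT2 (1.24) and PLIN2 (−0.54). For 12 clock and melatonin genes they were HLF (1.19), ASMT (−1.44), NPAS2 (3.96) and CLOCK (0.73). For 12 glycolysis genes they were PFKM (1.20), ENO1 (−0.77), LDHA (−0.75) and ENO2 (−0.56). For 12 stress genes they were JUN (−1.66), HSPA5 (−0.88), HSPA2 (−1.20) and EGR1 (1.40). For 13 identity genes of Müller glia they were YAP1 (2.32), STAT3 (0.66), SOX8 (−1.24) and NFIA (1.43). The 3 measured non-visual opsins were OPN3 (1.34), OPN4 (−0.68) and RRH (0.20). Among the genes of these 7 lists named here, ELFN2, STBD1, PLIN2, EGR1, YAP1, NFIA, OPN3 and RRH had opposite signs in the 2 libraries. The cone opsin list had no symbol shared by both species.

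Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower in cones, with a smallest adjusted p of 0.683. Adjusted over the list alone, 14 list genes were higher and 8 lower. These are totals of separately adjusted lists, so they carry no error rate of their own. They include SLC6A13 and MAFA, each with 0 UMIs in both classes of 1 library. With doublets kept these were 6 and 6, and with RLE size factors 7 and 7. At an unadjusted p under 0.05 there were 229 higher and 162 lower of 8575 genes, no larger a share than 0.05 gives without any difference. DESeq2 called 36 and 26, and gave no adjusted p for 3159 genes. Without the expression filter edgeR called 81 and 52. Across genes, the log2 ratios of cones to rods in the 2 libraries had Pearson's r of 0.0533 and a Spearman correlation of 0.0178, and 46.8% of genes had the same sign in both. Genes are not independent replicates, so no p is attached to these.

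**Figure D2:**
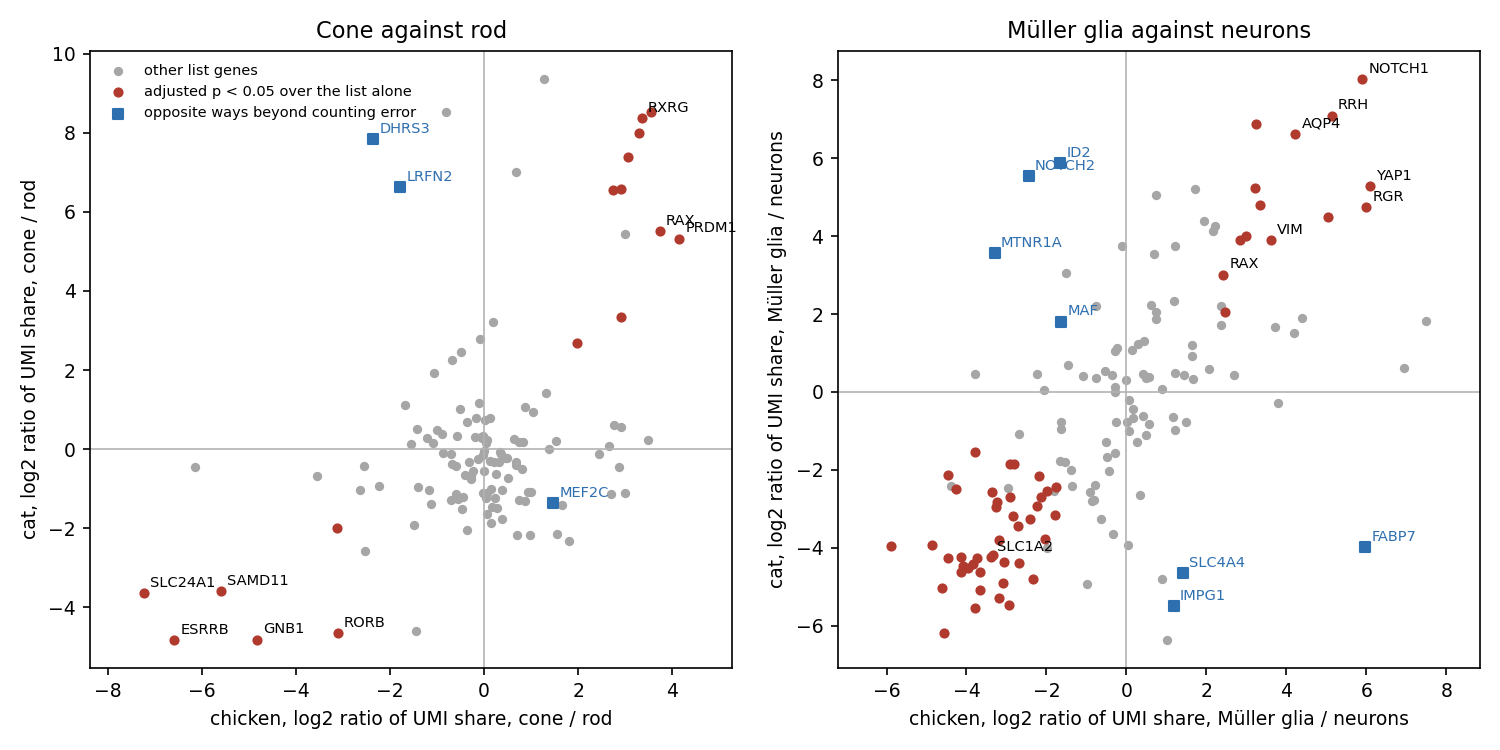
Log2 ratio of UMI share in the chicken (x axis) and the cat (y axis) for list genes with UMIs in every class compared, 126 for cones against rods (left) and 151 for Müller glia against neurons (right). Red points passed adjusted over the list alone, blue squares went opposite ways beyond counting error, and grey points are the other list genes; RAX lies at 3.73 and 5.51 on the left.

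Müller glia differed from neurons in both libraries in some genes of glial and progenitor identity. NOTCH1, the receptor of the Notch pathway, was higher in Müller glia by 7.01 log2 units (SE 0.88), and YAP1, the effector of the Hippo pathway, by 5.86 (SE 0.78). The Notch target HES1 was higher by 4.24 (SE 0.69), and VIM, the intermediate filament of glia, by 3.93 (SE 0.65). RGR, from the visual cycle list, was higher by 5.52 (SE 0.82), and RRH, from the list of non-visual opsins, by 6.29 (SE 0.96). No gene passed over all 10302 genes tested, and these calls too are those adjusted over the list alone.

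Of 20 measured identity and reprogramming genes, 7 were higher in Müller glia and 0 lower, and LHX2 (4.37), ID4 (4.95) and NFIX (5.20) completed the 7. The others did not pass. Among them, NOTCH2 (−2.44 in the chicken, 5.53 in the cat) and ID2 (−1.66 and 5.88) went opposite ways. Of 14 homeostasis genes, 3 were higher: the water channel AQP4 (5.49, SE 0.96), GPR37 (3.67, SE 0.77) and the carbonic anhydrase CA2 (3.54, SE 0.93). The glutamate transporter SLC1A2 was lower (−3.63, SE 0.69). RAX (2.89) and SIX6 (2.45) were higher among 29 photoreceptor transcription factors. In that list 13 were lower, among them PRDM1 (−5.64, SE 0.86), CRX (−3.84, SE 0.65) and ESRRB (−3.51, SE 0.71).

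Many genes of the photoreceptor lists were lower in Müller glia than in all neurons, of which rods were the largest part in the cat. Against bipolar and amacrine nuclei alone the lower calls over all lists fell from 48 to 9, and RGS9 and FSCN2 changed sign. Of 16 phototransduction genes, 15 were lower, among them SLC24A2 (−5.10), GUCA1A (−3.57) and GUCA1B (−4.51). Of 13 outer segment genes, 8 were lower, among them PRPH2 (−4.10) and CDHR1 (−4.71). Of 18 ribbon synapse genes, 10 were lower, among them PPEF2 (−3.81), SV2B (−3.98), CACNA2D4 (−4.64) and STX3 (−3.29). Of 18 visual cycle genes, RGR alone was higher and none lower. RBP3 (−3.36), ALDH1A1 (3.33) and ALDH1A3 (2.89) had the next smallest p there. Of 4 non-visual opsins, RRH was higher and OPN3 lower (−2.93, SE 0.58), and OPN5 (−2.50) and OPN4 (−0.55) did not pass. The sign of OPN4 differed between the chicken and the cat.

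In 4 lists no member passed for Müller glia against neurons. For 9 carotenoid and oil droplet genes the smallest p belonged to DGAT2 (−2.81), STBD1 (−1.79), SCARB1 (1.07) and SCD (−1.50). For 13 clock and melatonin genes they belonged to ASMT (−3.55), AANAT (−3.31), MTNR1B (2.46, with 0 cat UMIs in both classes) and CRY2 (1.02). For 12 glycolysis genes they belonged to LDHA (1.46), ENO2 (−1.13), HK1 (−1.06) and ENO1 (0.93). For 13 stress genes they belonged to FOS (2.27), JUN (2.26), HSPA2 (1.66) and DDIT4 (1.97). The signs of HSPA2 and DDIT4 differed between the chicken and the cat.

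Over all genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower in Müller glia, with a smallest adjusted p of 0.170. Adjusted over the list alone, 14 list genes were higher and 48 lower, again as totals of lists adjusted separately. At an unadjusted p under 0.05 there were 466 higher and 730 lower of 10302 genes. DESeq2 called 392 and 401, and gave no adjusted p for 600 genes. With bipolar and amacrine nuclei alone as the neurons, 12 list genes were higher and 9 lower. Of the 62 called against all neurons, only 19 still passed. A further 40 kept their sign without passing, 2 changed sign, and the remaining gene had no value there. Across genes, the log2 ratios in the 2 libraries had Pearson's r of 0.344 and a Spearman correlation of 0.254, and 57.9% of genes had the same sign.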

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

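The rule that picked out genes going opposite ways, the comparison with bipolar and amacrine nuclei and the tests of free RNA were chosen only after the results were seen. A gene went opposite ways when its log2 ratio between the classes lay beyond 1 unit, with its whole counting interval, in both libraries and with opposite signs. With 1 library per species these differences between chicken and cat were not tested. Over all genes, 73 of 8575 met the rule for cones against rods and 291 of 10302 for Müller glia against neurons. Among list genes it was 3 of 155 and 7 of 179.

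For cones against rods, the opposite genes were LRFN2, a synaptic adhesion protein, at −1.79 in the chicken and 6.62 in the cat. DHRS3, a retinal reductase, stood at −2.37 in the chicken and 7.84 in the cat, the latter on 121 and 4 UMIs. MEF2C, a transcription factor, stood at 1.47 in the chicken and −1.36 in the cat.

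For Müller glia against neurons, 3 genes were higher in chicken glia and lower in cat glia. IMPG1, a matrix proteoglycan of photoreceptors, stood at 1.18 in the chicken and −5.50 in the cat. SLC4A4, a bicarbonate cotransporter, stood at 1.41 and −4.65, and the fatty acid carrier FABP7 at 5.97 and −3.98. The other 4 were higher in cat glia. ID2 stood at −1.66 in the chicken and 5.88 in the cat, and NOTCH2 at −2.44 and 5.53. MAF stood at −1.63 and 1.81, and the melatonin receptor MTNR1A at −3.30 and 3.56, the latter on 10 and 7 UMIs.

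Technical explanations were weighed for these 7 genes in Müller glia. Rods make up most neuronal nuclei of the cat and few of the chicken's (79.6% and 4.43%). The ratios weigh classes by UMIs, of which rods held 8699715 of 17159774 in cat neurons and 799805 of 26400961 in chicken neurons. Yet all 7 kept opposite signs beyond counting error against bipolar and amacrine nuclei, which argues against rods as the whole cause. Beyond 1 log2 unit 5 of the 7 kept them. In the cat, FABP7 went from −3.98 to −1.36 (−2.88 to −0.12) and MAF from 1.81 to 0.35 (0.07 to 0.62), so the neurons chosen change the size. Bipolar and amacrine nuclei were 737 and 516 in the cat against 2119 and 4485 in the chicken. By UMIs, which set their weight, they held 2469948 and 3202990 in the cat and 6020897 and 9452020 in the chicken. The balance of bipolar and amacrine nuclei was not held fixed, so a part of it in the differences is not excluded. Free RNA in Müller glia nuclei was predicted to leave most of the genes without a clear lead over microglia and immune nuclei. This was met: 3 of 7 were more than 1 log2 unit higher in Müller glia beyond counting error. The prediction is also met by genes lower in Müller glia than in microglia, so meeting it does not speak for free RNA. The 3 with a lead (IMPG1, SLC4A4 and FABP7) were all of those higher in the chicken, by 3.80, 3.54 and 4.81, which argues against free RNA for them. Of the 4 higher in the cat, ID2 (−2.50) and MAF (−1.87) were lower in Müller glia than in microglia, of which there were 21 nuclei. NOTCH2 was higher in Müller glia by 0.96 (0.27 to 1.74), and MTNR1A had 10 and 0 UMIs, which give no ratio. Against bipolar and amacrine nuclei of the cat, 3 of these 4 were higher by more than free RNA shared by all nuclei would give at their UMIs per nucleus (0.47): ID2 by 6.61, NOTCH2 by 4.22 and MTNR1A by 3.77. MAF was not, so free RNA is not excluded for the 4 as a set. A species difference also stays open, untested.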

How the results depend on the processing

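The tests with clusters made from genes other than the one tested, and with bipolar and amacrine nuclei as the neurons, were chosen only after the results were seen; all other alternatives were planned. The cone-rich chicken and rod-rich cat kept their order in every alternative run. The rod share moved to 18.3% and 91.0% with at least 1000 UMIs, and in the cat to 94.1% with doublets kept. With at least 1000 UMIs, chicken shares moved to 17.1% Müller glia, 26.5% amacrine, 9.05% bipolar, 14.5% cone, 2.17% horizontal, 2.47% microglia, 3.39% oligodendrocyte and 10.5% ganglion cells. Those of the cat moved to 9.23% Müller glia, 7.24% amacrine, 10.5% bipolar, 5.77% cone, 2.23% horizontal, 0.394% microglia, 0.584% ganglion cells and 58.5% rod. The bipolar share, higher in the chicken by default, was there higher in the cat, and the horizontal shares no longer differed beyond counting error. Fewer shallow nuclei are kept there by construction. At resolution 0.5 the chicken had 37.1% amacrine, 11.4% bipolar and 1.36% horizontal, the last no longer above the cat's 1.52%, and at resolution 2 it had 23.2% amacrine and 2.97% rod. With doublets kept, the chicken had 14.7% bipolar, 3.28% microglia and 3.27% oligodendrocyte, and the cat 7.84% bipolar, 4.31% cone and 68.4% rod. In Oreochromis, amacrine nuclei were 11.3% at resolution 0.5, 1.35% at resolution 2, 10.9% with at least 1000 UMIs and 0.796% with doublets kept. Its oligodendrocytes were 12.1%, 10.9%, 13.7% and 10.7% in that order, and its ganglion cells 0% in all but the first. Apart from the UMI minimum, the cause was not tested.

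Stricter opsin calls gave 10.1% for chicken OPN1MSW, which no other opsin opposed, and 77.8% for cat OPN1LW, and thinning to 1000 UMIs gave 10.3% and 71.4%, where fewer UMIs per nucleus lower the share by construction. OPN1SW stayed inside its interval under both.

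No gene passed over all genes in edgeR with RLE factors, 1000 UMIs, doublets kept, exact symbols or either added test. DESeq2 called 36 higher and 26 lower genes for cones against rods, and 392 and 401 for Müller glia. Without a filter edgeR called 81 and 52 for cones against rods and 0 and 0 for Müller glia. List genes higher in cones, adjusted over the list alone, were 14, and 7 with RLE factors, 23 without the filter and 6 with doublets kept. Those lower were 8, and 7, 12 and 6 in that order. Of the 22 genes, 10 no longer passed with doublets kept: GNB1, GNB3, CNGA3, GUCA1C, SLC24A1 and SLC24A2 (list-adjusted p 0.0578), SALL1, SALL3, TBX2 and C1QTNF5. With RLE factors 8 no longer passed: GNB3, CNGA3, GUCA1C, SLC24A1 and SLC24A2 (0.0772), RBP4, SALL1 and SALL3. With DESeq2 5 no longer passed: MAFA, C1QTNF5, SLC6A13, KCNJ2 and VEGFA. All kept their sign. Those higher in Müller glia were 29 with DESeq2, and those lower were 9 against bipolar and amacrine nuclei, which leave photoreceptors out by construction. There only 19 of the 62 genes still passed. RGS9 (0.27) and FSCN2 (0.26) reversed, 40 others kept their sign without passing, and the remaining gene had no value. For the other changes the cause was not tested. RLE factors shifted the median log2 value of all genes by −0.11 for cones against rods and 0.17 for Müller glia. Exact symbols changed nothing, since no fish library entered the fits. Without either library no residual degrees of freedom were left, so each library's ratio stands alone, without a test. The tests of birds against fish were not run under any alternative. In simulated data of this size, adjusted over all genes, changes of 8-fold were recovered for 1 of 50 genes in cones against rods and 5 of 50 in Müller glia. The list-alone adjustment was not simulated.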

Other observations

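The tests of the rod share and of free RNA in Oreochromis were chosen only after the results were seen, as were the genes named in this part. Some numbered clusters of the other libraries carried strong single genes. In Oreochromis, a cluster of 75 nuclei held the highest levels of PDE6C (218 CPM), the cone phosphodiesterase, and of CNGA3 (170 CPM, Poisson interval 101 to 269), the cone channel subunit. The same cluster was highest in the matrix proteoglycan gene IMPG2 (265 CPM, 176 to 383). Its 1 scored cone marker, PDE6C, was raised, but a name needed 3 raised markers. A cluster of 59 nuclei was highest in the endothelial receptor KDR (938 CPM, 699 to 1234), in VEGFA and in the stress genes FOSB (3147 CPM) and ATF3 (1122 CPM). It was also highest in SLC1A2 (1030 CPM, 778 to 1338) and SOX2 (478 CPM, 313 to 701), from the lists of Müller glia genes. KDR was the only endothelial marker scored, so no cell type is read from these values.

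In the duck, TTR, the transthyretin gene of pigment epithelium and other tissues, reached 3649 CPM (3400 to 3912) in a cluster of 41 nuclei, against a median of 24.0 over 38 clusters. In the budgerigar, FOXP2 reached 6074 CPM (5332 to 6889) in a cluster of 39 nuclei, against a median of 85.8 over 29 clusters. In the chicken, FABP7 stood at 319 CPM in Müller glia and 197 CPM in oligodendrocytes, and at 8.75 CPM in rods. IMPG1 stood at 1058 CPM in chicken Müller glia and 2184 CPM in chicken cones, against 17.8 CPM in cat Müller glia.

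Rods were most of the cat's photoreceptor nuclei and a minority of the chicken's. Among nuclei with at least 1000 UMIs the gap in rod share was 72.8 percentage points, so cat rods of 500 to 1000 UMIs are not its whole source. Since 4003 cat rods stood beside 395 cones there, this cutoff could hardly have closed the gap. No more is concluded from it about depth. A loss of shallow chicken rods below the minimum cannot be told apart from few rods, since no chicken barcode analysed here held fewer than 500 UMIs. With doublets kept the gap was 71.7 points. The 879 chicken and 645 cat nuclei removed were too few to close it whatever their class. This comparison therefore shows only that their removal changed the gap little. Whether the gap may belong to the species, or to these retinas, the region sampled or the recovery of nuclei, cannot be told apart with 1 library per species.

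UMIs of PDE6G, CNGA1, GUCA1B and AIPL1 lay in all 31 Oreochromis clusters, whereas PDC (41 UMIs) and PDE6C (45 UMIs) lay in 12 and 10. This is not particular to phototransduction genes, since genes with many UMIs reach every cluster more easily. The bipolar markers VSX1 (2356 UMIs) and PRKCA (2753 UMIs) lay in all 31 too. Free photoreceptor RNA would put phototransduction genes at like levels in unrelated classes. Over 9 genes with at least 100 UMIs, the median absolute log2 difference between amacrine and oligodendrocyte nuclei was 0.19, and 8 lay within 0.5, so free RNA is a candidate explanation for those nuclei. An even background does not account for CNGA1 in a cluster of 391 nuclei, at 1686 CPM (1544 to 1837) against a median of 778 over clusters. SLC24A2 was an exception, 0.98 higher in amacrine nuclei (0.60 to 1.36), and CNGA1 stood at 669 and 803 CPM. Nuclei of mixed clusters, in a library where 69.2% of nuclei stayed unnamed, are not excluded by this value.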
